A study of Mus musculus with 9 samples.

How the data were processed

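RNA from submandibular salivary glands of female C57BL6/J mice aged 12 weeks was hybridised by the authors to Clariom S mouse arrays, whose probes are summarised into transcript clusters, each standing for the transcripts of a gene. The labels place the 9 arrays in 3 groups of 3 biological replicates: glands taken on day 3 after mock surgery, on day 3 after partial resection and on day 14 after partial resection. A day 14 mock group and unoperated glands were not analysed here, so at day 14 the effect of resection is not separated from the time since surgery. Replicate numbers come from the labels.

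The deposited values are on the log2 scale. Per the labels, the authors made them with Transcriptome Analysis Console 4.0 and RMA (robust multi-array average), which subtracts background, brings the arrays to a common distribution and summarises the probes of each transcript cluster. The genome build and the annotation version are not given in the sources used here, so no coordinates are printed. The deposited table holds 28846 rows, of which 6640 are control rows. The controls were left out of all tests, and 22206 transcript clusters were tested. Of these, 19572 carry 1 gene symbol and 2634 carry no symbol in the tables used here, and 55 symbols have more than 1 transcript cluster. Symbols are RefSeq gene names of assembly GRCm38.p6, found through the Entrez gene identifier in the table of probe genes for this platform. A transcript cluster for which this lookup gave no name counts as without a symbol. The RefSeq names also served to look up older symbols.

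The processing limits what the values can show. The highest value, 19.93, acts as a ceiling and was reached on all 9 arrays by 17 transcript clusters and on at least 1 array by 29. For these a change is either not measurable or only a lower bound of its size. In total, 337 tested transcript clusters exceeded 16 on the log2 scale, the most that a scanner with a range of 16 bits can record. If such a scanner was used, the scale was stretched at some step, which the sources used here do not describe. A log2 difference is therefore given on the deposited scale and is not a calibrated fold change. The table has no detection calls. The number of arrays limits the precision.

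Genes were tested with limma 3.58.1 in R 4.3.3, with all 9 arrays in 1 linear model, a mean per group, and empirical Bayes moderation of the variances (6 residual and 6.63 prior degrees of freedom). The 3 comparisons were day 3 resected against mock, day 14 resected against mock, and day 14 resected against day 3 resected. The mock arrays cancel in the last comparison, which is therefore also the test of whether the differences from mock differ between the days. P-values were two-sided and adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. Changes are given as log2 difference ± standard error (SE), and group levels as mean ± SD with n = 3. Replicates are the labels' biological replicates.

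The design, the gene lists and the rule for named genes were fixed before the data were examined. There were 30 gene lists with 490 genes, of which 449 were measured; the remaining genes were not analysed here. Lists were tested with camera, which compares a list's genes with all others, at a preset correlation between genes of 0.01, and adjusted over the 28 lists with at least 3 measured members. The lists of mucous cells of the sublingual type and of red blood cells had too few members for a test. Camera with an estimated correlation and fry, a test of whether a list's genes move on balance in 1 direction, were run beside it. The preset correlation is low for several of these lists, so the p with an estimated correlation is printed with each list whose call it ended. A list used 1 transcript cluster per gene, the one with the highest mean over all arrays. The lists cover secretory, ductal and myoepithelial cells, matrix, immune cells, inflammation, cell cycle, stress, metabolism, vessels, nerves, and markers of tissue that could be carried along in dissection (fat, skeletal muscle, lymph node).

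Named genes were, for each comparison, the 6 with the largest rise and the 6 with the largest fall past the threshold whose groups did not overlap. This rule was limited to transcript clusters with 1 gene symbol, leaving out symbols of predicted or unnamed genes (such as those ending in Rik), so larger changes of transcript clusters without a symbol are not ranked by it. Named as well were up to 3 members of each list past its threshold, and a fixed panel of salivary, matrix and immune genes. Spp1, which belongs to that panel, is not analysed here. The rule gave 138 gene results, of which 114 passed the threshold and 34 lost the call when 1 array was left out. List members among those 34 are counted in their list, and most are not used as examples.

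Alternatives were quantile normalisation or median centring of the deposited values, a filter on the dimmest 30% of transcript clusters, an intensity trend or robust variances in the moderation, array weights, the replicate number as a block, unmoderated statistics, only the groups compared, thresholds with a minimum of 2-fold, other list tests, and leaving out each array in turn. A model with the level of Dcpp3 on each array as a covariate and a fit without transcript clusters at an array maximum were added after seeing the data. The pipeline was tested on simulated data with 22206 transcript clusters, drawn around the mock means with the spread of the data. In the group standing for day 3 resected, 200 of them were changed, 50 by each size. Over 5 runs the pipeline recovered 1.2% of changes of 0.5 log2, 36.4% of changes of 1 log2, 98.4% of changes of 2 log2 and 100% of changes of 4 log2, with 4.6 false calls per run. These shares depend on how many transcript clusters change. The real comparison called 1393, so they are not its sensitivity. A list shifted by 1 log2 in the group standing for day 14 resected was called in 5 of 5 runs. Of 135 tests of the other lists, 0 gave a call. Genes were drawn independently of each other there, so the 0 calls do not show how camera behaves for lists of correlated genes. The estimated correlation in the data was 0.656 for cell cycle and 0.746 for granular convoluted tubule products. Figures were drawn with matplotlib 3.10.9.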

Results

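The submandibular gland is a major salivary gland whose serous acini secrete a watery saliva and whose granular convoluted tubules, a duct segment of rodents, store growth factors and kallikreins. The data describe gene expression in this gland after part of it was removed, at an early (day 3) and a later (day 14) time, beside mock surgery sampled on day 3. Each of the 3 groups has 3 arrays. Median log2 values of the tested transcript clusters ran from 5.09 to 5.24 over the 9 arrays, and arrays of the same group correlated at 0.985 to 0.990 across transcript clusters. The main axis of variation held 42.9% of the variance and set the day 3 resected arrays (scores of 44.5 to 71.3) apart from the mock and day 14 arrays (scores of -38.9 to -18.2). The Y-linked genes Uty, Kdm5d and Eif2s3y stayed at or below 3.13 on every array, and the labels give female mice. Transcript clusters of Prol1, Pip, Car6 and Klk1, all abundant products of the gland, sat at the array maximum in all groups, so no change of these could be measured.

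Day 3 resected against mock asks what removal of tissue adds to surgery itself. On day 3, resected glands had higher levels of acute phase, macrophage, matrix and cell cycle genes and lower levels of several secretory products of the granular tubules. Among genes with a symbol, the largest rise was that of Lcn2, an iron-sequestering acute phase protein, at 7.12 ± 0.35 log2 (mock 8.91 ± 0.30, day 3 resected 16.03 ± 0.40; adjusted p = 3.2e-07). Of all transcript clusters, TC0500001025.mm.2, without a symbol, rose most (8.28 ± 0.62). Among genes with a symbol Lcn2 was followed by the secreted chaperone Clu (6.54 ± 0.31), the metalloproteinase inhibitor Timp1 (6.46 ± 0.37), the chemokine Ccl9 (5.79 ± 0.40), the matrix glycoprotein Tnc (5.57 ± 0.78) and the macrophage elastase Mmp12 (5.48 ± 0.45). The largest falls under the naming rule were those of Jchain, the joining chain of secreted antibodies (-6.88 ± 1.60), Nudt22 (-3.02 ± 0.30), Egf (-2.94 ± 0.59), the kallikrein Klk1b16 (-2.54 ± 0.60), Tmigd1 (-2.37 ± 0.28) and the kallikrein Klk1b27 (-2.29 ± 0.44). Of 22206 transcript clusters, 1393 passed the threshold, 1092 of them higher (78.4%) and 301 lower after resection, and 1175 differed by at least 2-fold. The balance of directions depended on scaling, with 973 higher and 452 lower after quantile normalisation and 1013 higher and 480 lower after centring on the array medians. Groups did not overlap for 23.0% of transcript clusters, against 10% by chance. Without day 3 resected replicate 3 the count was 850, with 744 higher and 106 lower.

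Genes of cell division rose together. Of 27 measured cell cycle genes, 26 rose and 0 fell (27 rose when adjusted over the list alone). The median was 2.91 log2 (camera adjusted p = 3.2e-34, adjusted p = 0.0573 with an estimated correlation). The kinase Cdk1 rose by 4.17 ± 0.72, the replication helicase subunits Mcm6 and Mcm5 by 4.16 ± 0.57 and 3.92 ± 0.36, and the proliferation marker Mki67 by 3.85 ± 0.59. The mock arrays differed among themselves here, with list means of 0.64, 0.50 and -1.14 around the mock mean in replicates 1, 2 and 3, against 2.33 to 3.61 in the day 3 resected arrays.

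Matrix genes were higher as well. Among collagens and interstitial matrix, 16 of 23 rose and 0 fell (20 rose when adjusted over the list alone). The median was 2.19 (camera adjusted p = 5.6e-26, adjusted p = 0.0570 with an estimated correlation). Col1a1 rose by 5.12 ± 0.58, Fn1 by 4.86 ± 0.57 and Col3a1 by 4.69 ± 0.42. In the list of TGF-beta response and activated fibroblasts, 5 of 18 rose and 0 fell (5 rose and 1 fell when adjusted over the list alone), including the collagen-associated Cthrc1 (4.22 ± 0.46), Tgfbi (2.38 ± 0.37) and Tgfb1 (1.80 ± 0.24). The list had a camera adjusted p of 1.1e-05 and an adjusted p of 0.0570 with an estimated correlation. Matrix proteases and their inhibitors had 9 of 20 members that rose and 0 that fell (16 rose when adjusted over the list alone), among them Timp1, Mmp12 and the membrane-bound collagenase Mmp14 (2.61 ± 0.37). That list had a camera adjusted p of 4.1e-12 and an adjusted p of 0.105 with an estimated correlation. Without day 3 resected replicate 3 the median was 0.38 for the TGF-beta list (0.64 with all arrays, 0.37 without mock replicate 3) and 0.75 for the proteases (1.14 with all arrays). The list of basement membrane genes was not called (adjusted p = 0.118), with 1 of 17 members that rose.

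Innate immune genes rose most broadly among macrophage markers, where 14 of 16 rose and 0 fell, over all genes and when adjusted over the list alone (median 2.63, camera adjusted p = 8.0e-26, adjusted p = 0.0187 with an estimated correlation). Lyz2 (lysozyme) rose by 4.42 ± 0.35, the integrin Itgam by 4.32 ± 0.31, the lipid receptor Trem2 by 3.71 ± 0.31 and the surface marker Adgre1 by 2.47 ± 0.24. Of the complement and acute phase genes, 11 of 16 rose and 0 fell by both adjustments, the same count over all genes and adjusted over the list alone (median 1.33, camera adjusted p = 4.1e-12, adjusted p = 0.0110 with an estimated correlation), with Saa3 at 4.29 ± 0.49 and Serpina3n at 3.78 ± 0.33 beside Lcn2. Inflammatory cytokines and chemokines had 8 of 20 members that rose and 0 that fell (10 rose when adjusted over the list alone; median 0.91, camera adjusted p = 1.1e-09, adjusted p = 0.0368 with an estimated correlation). Among them were chemokines that attract monocytes, with Ccl8 at 5.16 ± 0.35, Ccl12 at 2.74 ± 0.45 and Ccl2 at 1.88 ± 0.32, while Il6 did not pass (0.59 ± 0.38, adjusted p = 0.451). Without day 3 resected replicate 3 the cytokine median was 0.51 and Il6 differed by 0.12. Neutrophil genes had 5 of 11 members that rose (8 when adjusted over the list alone), including Retnlg (4.53 ± 0.43) and S100a8 (2.86 ± 0.36). The neutrophil median was 0.98, and 1.61 without day 3 resected replicate 1. The list had a camera adjusted p of 1.3e-08 and an adjusted p of 0.0570 with an estimated correlation.

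Smaller immune and vessel lists were also called by camera but not with an estimated correlation. Interferon response genes had 6 of 18 members that rose (9 when adjusted over the list alone), such as Oas1a at 1.50 ± 0.30, with camera adjusted p = 3.3e-07 and adjusted p = 0.106 with an estimated correlation. T and NK cell genes had 3 of 18 that rose (4 when adjusted over the list alone), with Il7r at 1.60 ± 0.32, camera adjusted p = 0.00235 and adjusted p = 0.0570 with an estimated correlation. Mast cell genes had 3 of 8 that rose by both adjustments, including adjusted over the list alone, with the protease Cpa3 at 2.59 ± 0.49, camera adjusted p = 0.00329 and adjusted p = 0.0687 with an estimated correlation. Antigen presentation genes had 2 of 11 that rose (6 when adjusted over the list alone), with the class II gene H2-Ab1 at 1.54 ± 0.28, camera adjusted p = 0.00119 and adjusted p = 0.197 with an estimated correlation. Endothelium and vessel growth had 3 of 21 that rose (5 when adjusted over the list alone), camera adjusted p = 0.00214 and adjusted p = 0.142 with an estimated correlation. Pecam1, a marker of endothelium, did not pass (0.57 ± 0.37), with 0.22 without mock replicate 2 and 0.99 without mock replicate 1 as extremes. The T and NK cell median of 0.24 was 0.39 without mock replicate 2, and the mast cell median of 0.64 was 0.41 without day 3 resected replicate 2.

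Products of the granular convoluted tubules were lower. Of their 12 measured genes, 8 fell and 0 rose, also when adjusted over the list alone (median -1.40, camera adjusted p = 3.8e-07, adjusted p = 0.231 with an estimated correlation). Egf went from 14.91 ± 0.96 to 11.98 ± 0.48 (adjusted p = 0.00917). The other 4, Klk1b5, Klk1b11, Klk1b22 and Klk1b26, sat at the array maximum in mock glands, so their differences are bounds only, and none of them passed. Ductal cell genes had a median of -0.41 with 1 that fell, the sodium channel subunit Scnn1g (-1.46 ± 0.27), and 1 that rose, Krt19 (1.04 ± 0.27). Adjusted over the list alone, 6 fell and 1 rose (camera adjusted p = 0.0261, adjusted p = 0.377 with an estimated correlation). The ductal call was lost without mock replicate 1 (adjusted p 0.109) or day 3 resected replicate 3 (0.0670), and the median was -0.13 without the latter and -0.27 without mock replicate 3. Of 15 serous acinar genes, 3 fell, among them the acinar transcription factor Bhlha15 (-1.19 ± 0.31, adjusted p = 0.0386) and the chloride cotransporter Slc12a2 (-1.15 ± 0.24), but the list was not called by camera (adjusted p = 0.115), while fry gave 0.0499. Of its members, 3 (Prol1, Pip and Car6) sat at the array maximum on all arrays and could not show a change, which weakens this test. The water channel Aqp5 did not pass (0.27 ± 0.34, from -0.03 without day 3 resected replicate 1 to 0.68 without mock replicate 3), nor did the basal and myoepithelial markers Krt5 (0.71 ± 0.33) and Acta2 (0.31 ± 0.29, from 0.07 without mock replicate 3 to 0.49 without mock replicate 1). Oxidative phosphorylation genes had a median of -0.26 with 1 of 24 that fell by both adjustments, adjusted over the list alone included (camera adjusted p = 0.0378, adjusted p = 0.333 with an estimated correlation, and between 0.0688 and 0.193 without mock replicate 1 or 2 or day 3 resected replicate 1; median -0.16 without mock replicate 2).

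Several of the falling genes lost the call when 1 array was left out, although they remained lower. In the fits that ended a call this way, Jchain differed by -7.13 to -5.51 and Egf by -2.69. Klk1b16 differed by -2.63 to -1.95 and Bhlha15 by -1.25 to -0.95. The call of Jchain ended without mock replicate 2 or 3 or day 3 resected replicate 1 or 2 (adjusted p 0.0547 to 0.0838) or with robust variances (0.170), and that of Egf ended without day 3 resected replicate 3 (0.0531). The call of Klk1b16 ended without mock replicate 2 or 3 or day 3 resected replicate 1 or 3 (0.0522 to 0.113), and that of Bhlha15 without mock replicate 2 or 3 or day 3 resected replicate 2 or 3 (0.0743 to 0.161) or with only the groups compared (0.0697). Lists for tissue that could be carried along in dissection were not called (adjusted p = 0.760 for adipocytes, 0.760 for skeletal muscle and 0.256 for lymph node), although the lymph node list's chemokine Cxcl13 rose by 3.17 ± 0.39. Dcpp3 belongs to the list of mucous cells of the sublingual type, which had too few members for a test. The level of Dcpp3 varied widely, at 5.80 to 8.17 on mock arrays and 16.70, 7.80 and 19.69 on day 3 resected arrays. With its level as a covariate, 466 genes passed, 442 higher and 24 lower. Because Dcpp3 itself differed between the groups, the covariate takes up part of the group difference. The lower counts therefore do not show which changes go with Dcpp3. The median of 5222 negative control rows was 4.70 ± 0.06 in day 3 resected and 4.46 ± 0.06 in mock arrays (exact permutation p = 0.1, the smallest that 3 against 3 arrays can give).

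**Figure D1:**
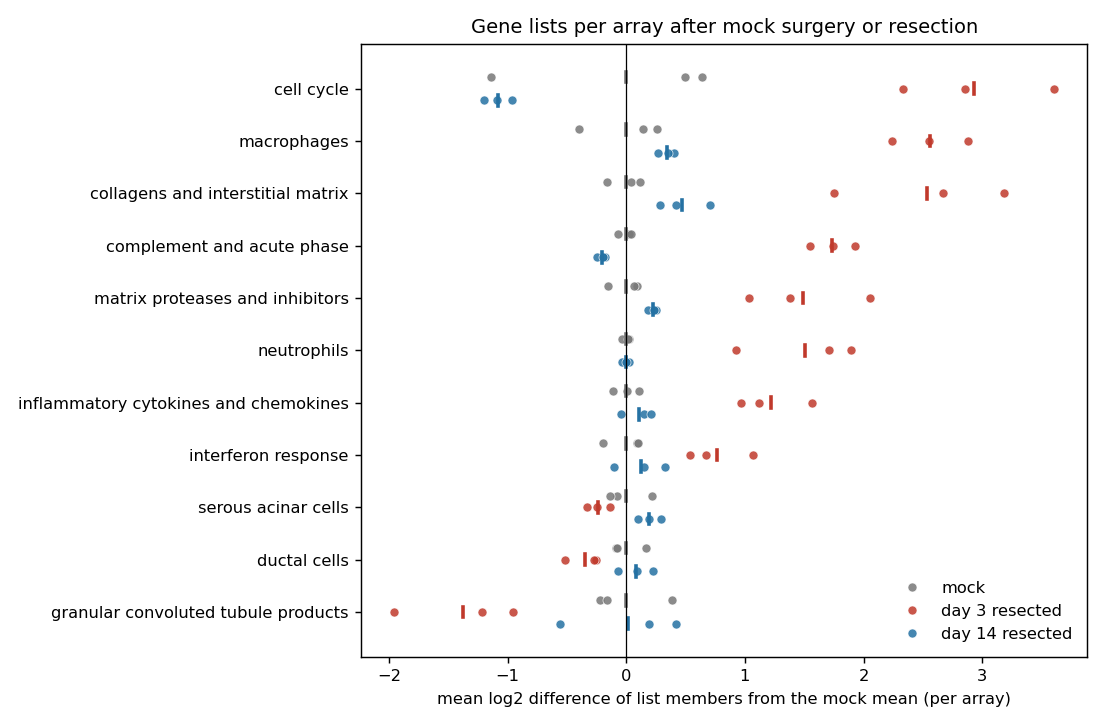
Mean log2 difference of the measured members of 11 gene lists from the mock mean (horizontal axis), with a point per array (3 per group) and a vertical bar at each group mean. Day 3 resected arrays (red) lie at 2.33 to 3.61 for the cell cycle list and at -1.95 to -0.95 for the granular convoluted tubule list, while day 14 resected arrays (blue) lie at -1.20 to -0.96 and -0.55 to 0.42.

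**Figure D2:**
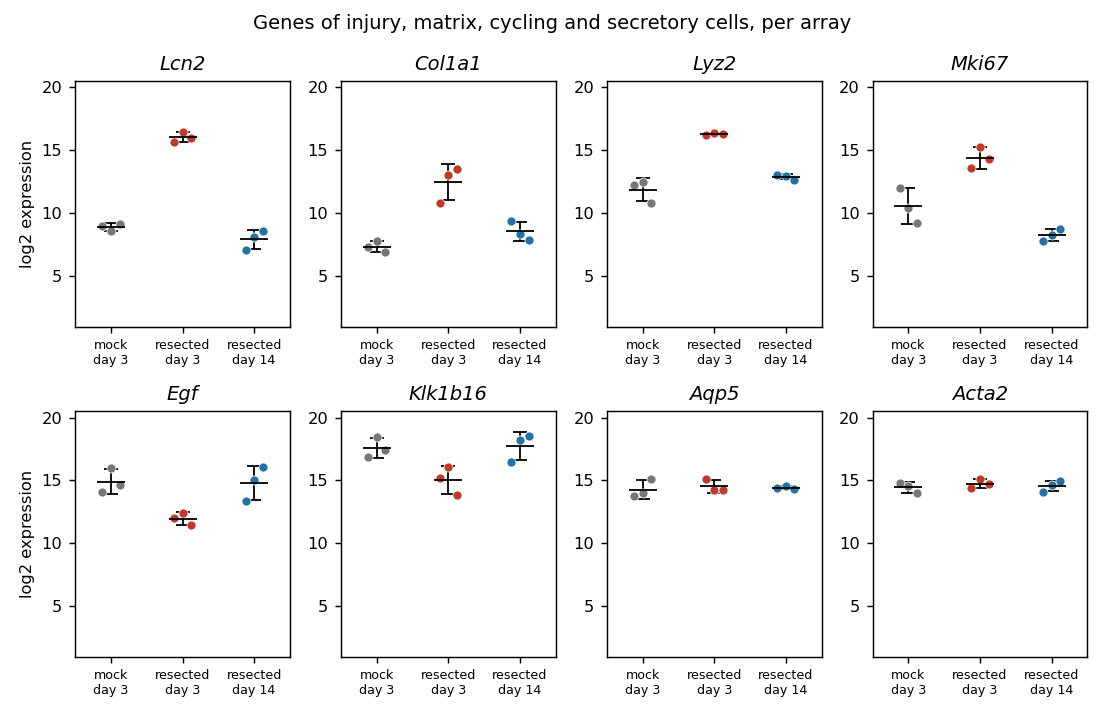
Log2 expression (vertical axis) of 8 named genes on each of the 9 arrays, with a point per array, the mean as a horizontal line and the SD as an error bar (n = 3). Lcn2, Col1a1, Lyz2 and Mki67 are highest in day 3 resected glands, Egf and Klk1b16 are lowest there, and Aqp5 and Acta2 did not pass the threshold in any comparison.

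Day 14 resected against mock asks what differs at the later time, with the limit that the mock glands were taken on day 3. Far fewer genes passed: 34, of which 22 were higher and 12 lower, and all 34 differed by at least 2-fold. Of the 34, 20 carry a gene symbol. The rest do not, among them 11 transcript clusters that were higher on both days at a median of 3.76 on day 14, of which 5 rose more than any gene with a symbol. Among genes with a symbol, the largest changes belonged to genes of the circadian clock and its outputs. Dbp, a transcription factor driven by the clock, fell by 7.50 ± 0.40 (mock 15.78 ± 0.56, day 14 resected 8.28 ± 0.86; adjusted p = 1.3e-06), and the period gene Per3 fell by 3.09 ± 0.23. Arntl, which encodes the core activator BMAL1, rose by 4.38 ± 0.38 (mock 7.13 ± 0.27, day 14 resected 11.50 ± 0.84; adjusted p = 1.6e-04), and its partner Npas2 rose by 3.21 ± 0.38. The cold-inducible RNA-binding protein Rbm3 fell by 1.86 ± 0.24. The other largest falls among named genes were those of the deubiquitinase Usp2 (-2.40 ± 0.34) and the clock repressors Ciart (-1.90 ± 0.27) and Bhlhe41 (-1.85 ± 0.25). The other largest rises among named genes were those of the Wnt antagonist Sfrp4 (2.21 ± 0.36), Sema4g (1.83 ± 0.31), the matrix protein Spon2 (1.72 ± 0.29) and the ribonuclease Ear10 (1.50 ± 0.22). Dbp, Per3, Arntl, Npas2 and Rbm3 passed without any 1 array.

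The others lost the call in at least 1 such fit. Bhlhe41 lost it without day 14 resected replicate 2 (adjusted p 0.0631), and Usp2 without mock replicate 1 or day 14 resected replicate 1 or 2 (0.0609 to 0.0899). Ciart (0.0501 to 0.0829), Ear10 (0.0593 to 0.0964) and Sema4g (0.139 to 0.192) each lost it without mock replicate 1 or 2 or any 1 day 14 resected array. Sfrp4 lost it without any 1 array (0.0784 to 0.194), and Spon2 without any 1 array other than day 14 resected replicate 1 (0.0762 to 0.213). Other settings ended calls as well, with array weights for Sfrp4 (0.0530) and Spon2 (0.0589), the replicate block for Sfrp4 (0.0662), Spon2 (0.0557) and Sema4g (0.0682), and only the groups compared for Spon2 (0.0674). The count of 34 became 58 without mock replicate 3 (25 higher and 33 lower), 20 without day 14 resected replicate 2 (14 and 6) and 22 without day 14 resected replicate 3 (13 and 9). It was 13 (11 and 2) with the level of Dcpp3 as a covariate, which was 17.06, 19.71 and 14.05 on the day 14 resected arrays, and 266 (110 and 156) at an unadjusted p under 0.05 with at least 2-fold, so the balance of directions was not stable. Groups did not overlap for 13.0% of transcript clusters, against 10% by chance.

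**Figure D3:**
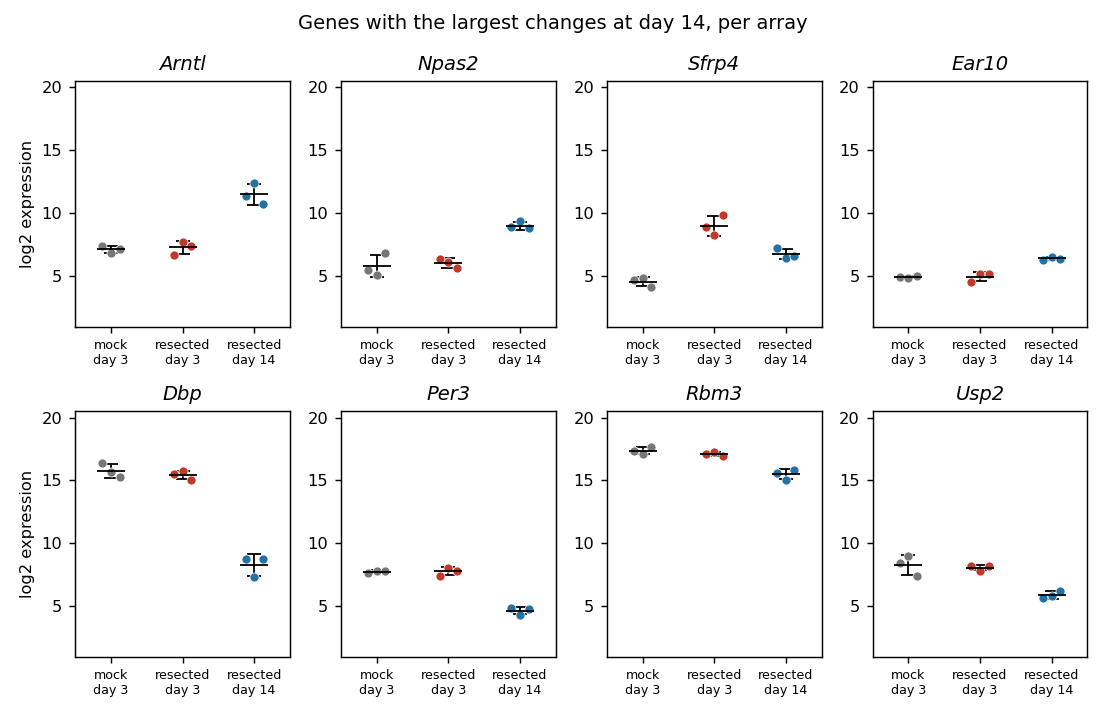
Log2 expression (vertical axis) of 8 of the genes with a symbol that changed most in day 14 resected against mock glands, with a point per array, the mean as a horizontal line and the SD as an error bar (n = 3). Dbp, Per3, Arntl and Npas2 lie at similar levels in mock and day 3 resected glands and differ on all day 14 resected arrays.

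Matrix, immune and cell cycle genes of the fixed panel did not pass the threshold at day 14. Against mock, Col1a1 differed by 1.20 ± 0.58, Col3a1 by 1.71 ± 0.42 (adjusted p = 0.220), Tnc by 0.84 ± 0.78, Adgre1 by 0.27 ± 0.24, S100a8 by -0.22 ± 0.36 and Ccl2 by 0.26 ± 0.32. Mki67 differed by -2.25 ± 0.59 (adjusted p = 0.257). Among salivary genes, Bhlha15 differed by 0.19 ± 0.31, Aqp5 by 0.16 ± 0.34 and Egf by -0.11 ± 0.59. Without 1 array, Col1a1 was 0.77 without day 14 resected replicate 1, Adgre1 0.07 and 0.45 without day 14 resected replicate 2 and 3, S100a8 -0.35 and -0.07 without day 14 resected replicate 1 and 2, and Bhlha15 between 0.01 without mock replicate 1 and 0.43 without mock replicate 3. Aqp5 turned negative without mock replicate 1 (-0.10) and Egf turned positive without mock replicate 2 (0.43) or day 14 resected replicate 1 (0.63). Camera called 7 lists, but 0 of them had a member past the gene threshold, and 0 of the 7 were called with an estimated correlation or by fry. Their medians were 0.18 for collagens and interstitial matrix (adjusted p = 0.653 with an estimated correlation), 0.32 for macrophages (0.415, and not called by camera without mock replicate 3 at 0.267, with a median of 0.18), 0.31 for antigen presentation (0.395), -1.03 for cell cycle (0.395), -0.26 for oxidative phosphorylation (0.395), -0.70 for immediate early genes (0.395) and -0.26 for myoepithelial and basal cells (0.653). Without 1 array the medians moved to as much as 0.47 for collagens (mock replicate 1), 0.49 for macrophages (mock replicate 2), 0.19 and 0.54 for antigen presentation (mock replicate 3 and 2) and -0.35 for immediate early genes (mock replicate 2). Adjusted over the list alone, 5 cell cycle and 5 immediate early genes were lower, as was 1 myoepithelial gene, and 2 macrophage genes, 1 antigen presentation gene and 1 matrix gene were higher. The myoepithelial list was not called by camera without mock replicate 1 or 2 or day 14 resected replicate 1 (adjusted p 0.0622 to 0.614), and its median ran from -0.40 to 0.04 in these fits. Its call also ended without the dimmest transcript clusters (0.0695), after quantile normalisation (0.0548), with array weights (0.0633) and with ranks (0.0912). The cell cycle list, whose 27 members were all lower than in mock, had a median of -0.73, -0.79 and -1.77 without mock replicate 1, 2 and 3.

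Day 14 resected against day 3 resected asks which of the early differences had receded. Among genes with a symbol, Lcn2, which had risen on day 3, was lower by the widest margin (-8.11 ± 0.35, adjusted p = 1.9e-07). It was followed by Dbp (-7.15 ± 0.40), the mitotic genes Cenpm (-6.74 ± 0.68), Pbk (-6.70 ± 0.79) and Ube2c (-6.57 ± 0.64), and Clu (-6.41 ± 0.31). The largest rises under the naming rule were those of Jchain (6.34 ± 1.60), Arntl (4.22 ± 0.38), the desaturase Fads2b (3.54 ± 0.34), the clock-linked repressor Nfil3 (3.21 ± 0.59), Retnla (3.12 ± 0.40), a product of alternatively activated macrophages, and Npas2 (2.97 ± 0.38). In all, 1394 genes passed, 310 higher and 1084 lower at day 14. After quantile normalisation 433 were higher and 930 lower, and without day 3 resected replicate 3 the count was 874, with 129 higher and 745 lower. Groups did not overlap for 25.4% of transcript clusters, against 10% by chance. Jchain lost its call without any 1 array other than day 14 resected replicate 2 (adjusted p 0.0533 to 0.109) and with robust variances (0.198), and its rise was 4.20 without day 14 resected replicate 1.

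By list, all 27 cell cycle genes fell (median -4.15, adjusted p = 0.0640 with an estimated correlation), with Mki67 at -6.09 ± 0.59 and Cdk1 at -5.52 ± 0.72. Of the macrophage genes 14 of 16 fell (median -2.34, adjusted p = 0.0268 with an estimated correlation), led by Itgam at -3.71 ± 0.31. Of the complement and acute phase genes 9 of 16 fell (median -1.52, adjusted p = 0.0103 with an estimated correlation), with Serpina3n at -5.30 ± 0.33. Collagens and interstitial matrix had 15 of 23 members that fell (median -1.78, adjusted p = 0.0864 with an estimated correlation), with the crosslinking enzyme Lox at -4.62 ± 0.35 and Col1a1 at -3.92 ± 0.58. Cytokines and chemokines had 7 of 20 that fell (0.0522 with an estimated correlation), interferon response 6 of 18 (0.214), matrix proteases 6 of 20 (0.208), neutrophils 5 of 11 (0.0741), TGF-beta response 4 of 18 (0.0864) and endothelium 2 of 21 (0.266), each value being the adjusted p with an estimated correlation. The endothelium list was also not called by camera without day 3 resected replicate 3 (adjusted p 0.131) or day 14 resected replicate 1 (0.121), or without the dimmest transcript clusters (0.145), and fry gave 0.0635. Its median of -0.18 was -0.27 without day 14 resected replicate 2, that of the proteases (-0.80) was -0.39 without day 3 resected replicate 3, and that of the cytokines (-0.61) was -0.94 without day 14 resected replicate 3. Adjusted over the list alone, the falls numbered 27 for cell cycle, 15 for macrophages, 11 for acute phase, 18 for collagens, 9 for cytokines, 8 for interferon response, 8 for proteases, 7 for neutrophils, 5 for TGF-beta response and 2 for endothelium.

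Products of the granular convoluted tubules were higher at day 14 than at day 3 for 7 of 12 members (8 when adjusted over the list alone; median 1.44, camera adjusted p = 4.4e-07, adjusted p = 0.250 with an estimated correlation), with Klk1b27 back at 14.39 ± 0.77 (2.30 ± 0.44) and Egf at 14.81 ± 1.37 (2.83 ± 0.59, lost without day 3 resected replicate 3 at 0.0640 or day 14 resected replicate 3 at 0.0519). Ductal genes had 5 of 17 members that rose by both adjustments, including adjusted over the list alone (median 0.42, camera adjusted p = 0.00499, adjusted p = 0.266 with an estimated correlation), led by Scnn1g at 1.42 ± 0.27. Bhlha15 rose by 1.38 ± 0.31, a call lost without day 3 resected replicate 2 or 3 or day 14 resected replicate 1 or 3 (adjusted p 0.0738 to 0.0885).

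Of the 1393 genes that differed from mock on day 3, 918 (65.9%) differed between day 14 and day 3 in the direction of mock, 823 of the 1092 risen and 95 of the 301 fallen genes, 0 moved further away and 475 did neither. Genes that went past mock to its other side are counted among the 918. Selecting genes on day 3 favours movement towards mock. In 50 simulated draws in which day 14 kept the day 3 means, at most 1 gene moved back, but those draws called a mean of 3392 genes on day 3, so this reference, added after the counts were seen, is a rough one. In the data, the median share of the day 3 change that was left at day 14 was 6.15% for risen and 30.2% for fallen genes. At day 14, 64.7% of the 1393 genes lay on the same side of mock as on day 3, and the rest did not. In the same direction, 16 genes passed against mock on both days, 14 higher and 2 lower, against 1.24 that independent sets of these sizes would share. Simulated draws with shared mock arrays and no real change shared at most 0, but without real change few genes can be expected to pass, so this says little. The 2 sets share the mock arrays, which by itself makes their changes correlate. The changes correlated at r = 0.247 over all transcript clusters, against 0.501 from shared mock arrays in 50 simulated draws without real change, but their covariance was 0.0591 against 0.0380, so these values do not settle how much of the likeness comes from the mock arrays. The mock arrays are too few to be split between the comparisons. Among the 16, selected for this result after their values were seen, Sfrp4 was higher by 4.44 ± 0.36 on day 3 and 2.21 ± 0.36 on day 14, Spon2 by 1.25 ± 0.29 and 1.72 ± 0.29, and Limd2 by 1.28 ± 0.21 and 1.23 ± 0.21. The day 14 calls of Sfrp4 and Spon2 were lost in the other fits given above. Echdc2 was lower on both days (-1.61 ± 0.23 and -1.77 ± 0.23), as was Dnase1 (-1.98 ± 0.25 and -1.52 ± 0.25), and the other 11 carry no gene symbol. The calls of Limd2, Echdc2 and Dnase1 were not followed gene by gene in the other fits. Their adjusted p at day 14 was 0.0474, 0.00507 and 0.0351. Neil3, a DNA glycosylase, went from higher on day 3 (1.65 ± 0.22) to lower on day 14 (-1.79 ± 0.22). The overlap was 10 with the level of Dcpp3 as a covariate.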

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

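The difference between the day 14 and day 3 resected groups was tested for every gene and list by the planned comparison, the splits were planned, and the tests of the unnamed transcript clusters were chosen after that result was seen.

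The changes from mock differed between the days for 1394 genes. They also differed for 12 gene lists, whose medians of day 14 minus day 3 were -4.15 for cell cycle, -2.34 for macrophages, -1.78 for collagens and interstitial matrix, -1.52 for complement and acute phase, -1.06 for neutrophils, -0.82 for interferon response, -0.80 for matrix proteases and inhibitors, -0.61 for inflammatory cytokines and chemokines, -0.37 for TGF-beta response and activated fibroblasts, -0.18 for endothelium and vessel growth, 0.42 for ductal cells and 1.44 for granular convoluted tubule products. With an estimated correlation 2 of these 12 lists kept their call, macrophages and complement and acute phase. The median of the negative control rows, which no comparison uses, was higher by 0.25 log2 in day 3 resected than in mock arrays.

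With 3 arrays against 3 there are 10 splits, so the share cannot be under 0.1. The real split gave 1393 genes for day 3 resected against mock, 34 for day 14 resected against mock and 1394 for day 14 against day 3 resected, and the highest of the other splits gave 0 in each, so that 1 of 10 splits gave as many genes in each comparison. For lists the real counts were 16, 7 and 12, the highest of the other splits gave 13, 8 and 15, and 1, 2 and 4 of the 10 splits gave as many. In the comparisons with day 14, a mixed split thus called more lists than the real one. A mixed split keeps part of the group difference and moves the rest into the spread within groups. Its 0 genes and its list counts are therefore not a reference without change, and they do not rank gene counts against list counts.

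A set of 11 transcript clusters without a gene symbol was higher in resected than in mock glands on both days with no overlap of arrays, at a median of 2.74 log2 on day 3 and 3.76 log2 on day 14. They make up 11 of the 22 transcript clusters that were higher at day 14 and 11 of the 16 shared calls, 8 have consecutive identifiers, and none was identified here, so it is open whether they are genes. TC0200004196.mm.2 rose by 5.87 ± 0.21 on day 3 and sat at the array maximum on day 14, where 6.05 is a lower bound. The array medians of the deposited values, 5.09 to 5.24, lie far closer together than these changes. This argues only against a scaling difference left in the deposited values. RMA brings arrays to a common distribution, so alike medians were set by the processing and do not show how the samples compared before it. All 11 were still called at day 14 after quantile normalisation, which could change little in arrays so alike. Genomic DNA or unspliced RNA carried into resected samples may be a source. The negative control rows were higher by 0.0928 log2 in day 14 resected than in mock arrays, with overlap between the groups, which does not settle this. All 11 clusters were higher at day 14 than at day 3 (0 of them called). The negative control median went the other way, at 4.55 ± 0.06 at day 14 and 4.70 ± 0.06 at day 3. The clusters thus did not follow the control rows between the days. Because 0 of the 11 were called there and the control rows were not tested between the days, this decides nothing about genomic DNA or unspliced RNA. A lasting effect of the resection is also open, as no test here separates it from how the samples were handled.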

How the results depend on the processing

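The Dcpp3 covariate and the removal of transcript clusters at the array maximum were chosen after seeing the data, and the other alternatives were planned. Among named genes, 1060 results under other settings kept direction and side of the threshold, 35 lost the call and 4 reversed. Leaving out 1 array kept 686, ended 127 calls, added 1 and reversed 14. For called lists, 342 and 199 results were kept and 43 and 11 lost. With 3 arrays per group, changes near 1 log2 were often missed in the simulated data, and values at the ceiling hide changes. Unless stated, the cause was not tested.

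Unmoderated statistics, which leave 6 degrees of freedom, gave 443 genes for day 3 resected against mock, 4 for day 14 resected against mock, 577 for day 14 against day 3 resected and 2 shared by both days. The Dcpp3 covariate, which costs a degree of freedom and is itself uneven between groups, gave 466 and 13 genes for the comparisons with mock and 10 shared by both days. For day 14 resected against mock, an intensity trend gave 56 genes and an unadjusted p under 0.05 with at least 2-fold gave 266. With an estimated correlation camera called 3, 0 and 2 lists in the order of the report, and fry called 0 at day 14 against mock. Without 1 array at a time, the counts ran from 850 to 1295 genes for day 3 resected against mock, 20 to 58 for day 14 resected against mock and 874 to 1386 for day 14 against day 3 resected, from 15 to 17, 6 to 9 and 11 to 14 lists, and from 12 to 16 genes shared by both days.

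Genes that reversed had not passed the threshold. In day 14 resected against mock, array weights turned Egf to 0.0203, Il6 to 0.00540 and Pecam1 to -0.0016. Quantile normalisation turned Aqp5 to 0.0391 in day 14 against day 3 resected, as did leaving out day 3 resected replicate 1 (0.19; range -0.27 to 0.19), which also turned it to -0.0343 in day 3 resected against mock (range -0.0343 to 0.68). In day 14 resected against mock, leaving out mock replicate 1 turned Aqp5 to -0.10 (range -0.10 to 0.57). Without mock replicate 2, Egf was 0.43, Il6 0.05 and Pecam1 -0.28, and without mock replicate 3 Acta2 was -0.12 and Pecam1 -0.0040. Without day 14 resected replicate 1, Egf was 0.63, Krt5 0.0821 and Il6 0.30, without replicate 2 Pecam1 was -0.04 and without replicate 3 Acta2 was -0.08. Ranges were -0.72 to 0.63 for Egf, -0.26 to 0.30 for Il6, -0.28 to 0.50 for Pecam1, -0.12 to 0.33 for Acta2 and -0.58 to 0.0821 for Krt5. In day 14 against day 3 resected, Acta2 ran from -0.39 to 0.0279, the latter without day 14 resected replicate 1.

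Replicate numbers do not pair the arrays: after removing group means, arrays with the same number correlated at -0.09 to 0.05 in 9 pairs. With the number as a block, 1283, 26 and 1297 genes and 16, 8 and 12 lists were called.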

Other observations

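The test of clock genes not yet looked at and the tests of mucous and parotid genes were set before their results were seen, and the other tests were chosen after. The interval around each correlation, the look at Amy1 and the look at acute phase levels at day 14 were also added after. Tests of the cell cycle genes below mock at day 14 were run too and are not weighed here. Leaving out any 1 mock array kept the median of that list between -1.77 and -0.73, and mock replicate 3, with a list mean of -1.14, lay within the range of the day 14 resected arrays.

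Genes outside the called lists changed on day 3 as well. Etv5, a transcription factor of FGF signalling, rose by 1.70 ± 0.31 while the list of progenitor and development factors was not called. The angiogenic factor Vegfa fell by 1.27 ± 0.27 while Ldha (1.18), Ndrg1 (1.32) and Pkm (0.95) of the same hypoxia and glycolysis list rose, and the list was not called (adjusted p = 0.157). Lists of B and plasma cells (0.553), nerve and Schwann cells (0.734) and ER stress (0.206) were not called either.

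In a list of 16 clock genes written after the largest changes were seen, 8 passed against mock at day 14, out of 34 transcript clusters in all, and all 16 differed in the direction of a shifted clock, with a median of 1.97 in that direction. The array medians of 5.09 to 5.24 argue only against a scaling difference left in the deposited values, since RMA made the arrays alike. The median of the clock genes was 1.99 after quantile normalisation, which could change little in arrays so alike. A shift of the whole clock, as from another time of day at collection, remains a candidate explanation. The 7 genes not looked at before (Clock, Cry1, Per1, Per2, Nr1d1, Nr1d2 and Hlf) all went in the direction set beforehand, but their median of 0.96 fell short of the 1 log2 that had been required. The lowest adjusted p among them was 0.0566, for Nr1d2. In day 3 resected against the same mock arrays these 7 also went in that direction, as did 14 of all 16. Direction alone is therefore not particular to day 14. Against the day 3 resected arrays, Hlf went the other way at day 14 (0.34). Its group means were 3.50 in mock, 2.85 in day 3 resected and 3.20 in day 14 resected arrays. All lie under the lowest negative control median (4.41), so the direction of Hlf says little in any comparison. A lasting effect of the resection is also open, because no day 14 mock group was analysed here; the median of 0.27 at day 3 bounds an effect at that day only, and collection times are not given in the sources used here.

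Dcpp3 was 5.80 to 8.17 on mock arrays, 16.70, 7.80 and 19.69 on day 3 resected and 17.06, 19.71 and 14.05 on day 14 resected arrays, and A2ml1 moved with it (14.36, 6.79 and 18.12, then 15.11, 19.30 and 11.84), as did the salivary protein Bpifa2 in part (12.80, 12.40 and 17.88, then 15.46, 19.93 and 14.27). Parotid tissue is argued against, since its abundant enzyme Amy1 was 6.89 to 8.46 on resected and 8.05 to 9.27 on mock arrays, while the correlation of 3 parotid genes with Dcpp3 within groups decides nothing by itself (r = -0.142, upper 95% bound 0.846, rho = -0.50, exact one-sided permutation p = 0.611 and 0.861, r = -0.02 without the 2 arrays farthest from the median). A response that scales with the acute phase is argued against as well, since on all day 14 resected arrays the complement and acute phase list lay below mock (-0.24 to -0.18) where Dcpp3 was high, and within groups r was -0.618 (upper 95% bound 0.58, rho = 0.0, exact one-sided permutation p = 0.750 and 0.639, r = 0.33 without those 2 arrays). Sublingual tissue, a neighbouring gland, may have been included in some resected samples, and the test leaves this open: 13 mucous cell genes gave r = 0.434 (upper 95% bound 0.952, rho = 0.50, exact one-sided permutation p = 0.222 and 0.250), which turned to -0.83 without the 2 arrays farthest from the median and so rests on those arrays. Among the 13, Tff1, Tff2, Tff3, Galnt12 and Muc5b stayed at or below 4.31, under the lowest negative control median (4.41). Creb3l1 (13.08 to 14.34) and Spdef (10.00 to 10.90) were high on mock arrays already. Their mean is therefore a weak test of sublingual tissue. Smgc, a mucin-like product placed in the list of sublingual mucous cells here, was 17.53 to 18.23 on mock and 15.33 to 18.63 on resected arrays. Being this high on mock arrays, it cannot mark sublingual tissue in the resected samples.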
